A study of Mus musculus with 9 samples.

How the data were processed

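Total RNA of 9 mouse samples was measured on Illumina whole-genome bead arrays, 3 arrays each of undifferentiated embryonic stem cells (mES), purified neonatal cardiomyocytes (CMp) and purified adult left ventricular cardiomyocytes (CMa). Per the labels, RNA was isolated with Trizol, checked on a Bioanalyzer and turned into biotin-labelled cRNA with an Ambion kit. The labels speak of primary cells, purified and cultured, and state that no treatment was used. They call the samples biological triplicates and do not say which animals or cultures were used, and age and heart region differ together between CMp and CMa.

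The deposited scanner table held, per the file headers, a mean bead signal intensity for each probe on each array, on the linear scale and without normalization between arrays, and the software that exported it is not given in the sources used here. Beside each intensity the deposited table gave, per the file headers, a detection p-value, which falls as the signal of its array rises. The deposited series matrix held log2 values that the authors normalized with lumi, per the submitters' processing notes, and its version and settings are not given in the sources used here. Array medians of that matrix were 7.407 to 7.408. Of its entries, 3775 (8.34%) differed by more than 0.1 log2 units from the scanner signals of the probe they are listed under, and each of these held the values of another probe, of the same gene in 2894 cases, of a different gene in 38 and with a probe without a single gene symbol in 843. Where the entry held a different gene and the gene had further probes, these correlated better with the scanner values in 9 of 14 cases, too few to settle which source is right. The scanner values, which carry the detection p-values, were used for the main results and the matrix as an alternative.

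Analysis was done in R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8). Background was estimated from the detection p-values (limma nec), an offset of 16 was added, and arrays were quantile normalized and log2 transformed. Probes with a detection p under 0.01 on at least 3 of 9 arrays were kept, 19707 in all, of which 16962 carried a single gene symbol from the array annotation and 2745 did not. For 4158 genes with several kept probes the brightest was used, giving 10800 genes, and the kept probes of a gene moved in opposite directions by at least 2-fold in 44, 63 and 19 genes for CMp against mES, CMa against mES and CMa against CMp. Fold changes below are those of the brightest probe, and other kept probes of a gene could give much smaller ones. A linear model with a mean per group was fitted to all 9 arrays (lmFit, eBayes), p-values were adjusted by Benjamini-Hochberg within each comparison, and genes with an adjusted p under 0.05 were called. Genes called and changed at least 2-fold were counted separately, and the F-test of the same fit asked whether a gene differed among the 3 groups. Where the tested probe was undetected on every array of a group, the fold change is given as a bound, written as at least, for which that group's values were raised to the lowest detected level of each array. At the other end, Myl3, Myl2, Tnnc1, Atp2a2, Cox6a2, Cox7a1, Lpl, Igf2, Hba-a1 and Dppa5a had a group mean over 15 log2 units, close to the highest level on the arrays, where any fold change can be compressed.

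In all, 27 gene lists with 497 members were fixed before the data were examined, of which 406 members were tested. They cover pluripotency, early lineage, cell cycle, ribosome biogenesis, chromatin, the sarcomere, calcium handling, ion channels, cardiac transcription factors, the fetal cardiac programme, energy metabolism, imprinted growth genes, the circadian clock, early response genes, sex-linked genes and markers of cell types of the heart. Each was tested with limma's camera at a preset correlation of 0.01 between genes, again with the correlation estimated from the data, and with fry. Estimating the correlation also refers each camera test to the residual degrees of freedom of the fit. Its p-values thus rose even for lists with an estimate below 0.01. For pluripotency in CMp against mES, at -0.02, the unadjusted camera p went from 4.2e-13 to 0.000188. A call lost under that setting therefore does not by itself show correlated genes. Genes named were drawn, by a rule set before the data were examined, from the 5 largest increases and decreases among called genes whose groups did not overlap, up to 3 called members with the largest changes of each list, anchor genes, and members that moved against their list where these numbered 5 or fewer. The anchors Tnnt2, Mki67 and H19 had no probe under that symbol and Dnmt3a had no kept probe. The overlap of the comparisons with mES was set against independent lists and against 200 simulated data sets that share the mES arrays.

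The methods were tested on simulated data, in which 10555 of 10741 genes were left unchanged in CMa. The groups compared below differ in far more genes, so the rates that follow may not hold for them. Of genes changed by 1.5, 2, 4 and 8 times, 15.6%, 78.3%, 97.9% and 97.9% were called in CMa against CMp, and 0% of unchanged genes, while fitted log2 changes were 0.834 to 0.904 of the true ones. In CMa against mES 13.3%, 71.7%, 89.6% and 95.7% of changed genes and 0.0947% of unchanged genes were called, with fitted log2 changes of 0.875 to 0.916 of the true ones. With 1 list shifted by 1 log2 unit, that list was called and of 23 lists sharing no member 0 were. The simulated genes varied independently of each other, so this does not test list calls where genes are correlated.

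The alternatives were the authors' matrix with each entry assigned to the probe whose scanner values it held, no background correction, median scaling, cyclic loess, an offset of 50, no or a stricter detection filter, the mean of a gene's probes, a replicate block, an intensity trend, fits of the compared groups alone, a test against 2-fold (treat), an estimated correlation and leaving out each array in turn. Added once values had been seen were the matrix under its own probe identifiers, a fit without probes that differ between the tables, and a fit of CMp replicate 1 with CMa replicates 1 and 2, in which the lone CMp array is assumed to vary like the other groups. A block for the array chip was not run, as the column names give no chip. Probes without a single gene symbol were left out of the gene results.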

Results

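Transcript levels were profiled in 9 samples of mouse cells, 3 from each of 3 groups. The groups were undifferentiated embryonic stem cells (mES), which are pluripotent cells of the early embryo kept in culture, cardiomyocytes purified from the hearts of neonatal mice aged 1 day (CMp), and cardiomyocytes purified from the left ventricle of adult mice aged 2 months (CMa). Cardiomyocytes are the contractile cells of the heart. Biotin-labelled cRNA from each sample was hybridised to an Illumina whole-genome bead array. The labels describe the cells as purified and cultured and state that none was treated. The median signal per array lay between 88.7 and 112.2, and 13781 to 17946 probes (30.4% to 39.6%) were detected per array, the 3 CMa arrays having the fewest. The labels call the arrays of a group biological triplicates without saying which animals or cultures they came from, so p-values measure the spread between these samples. Levels below are log2 intensities after background correction and quantile normalization, given as mean ± SD (n = 3 arrays per group), and log2 changes are given ± SE from the limma fit.

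The 3 groups were well separated. Arrays of a group correlated with each other at r = 0.988 to 0.995 (mES), 0.965 to 0.995 (CMp) and 0.973 to 0.985 (CMa) across the 10800 genes tested, and the first principal component, which set mES apart from both cardiomyocyte groups, held 76% of the variance. CMp and CMa arrays correlated at 0.85 to 0.884, against 0.633 to 0.648 for CMp with mES and 0.555 to 0.58 for CMa with mES. The second component, which parted CMp from CMa, held 18.4% of the variance. By limma's F-test, 9496 genes (87.9%) differed among the 3 groups.

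The first comparison asked which transcripts differ between neonatal cardiomyocytes and undifferentiated stem cells. Neonatal cardiomyocytes carried the transcripts of the contractile apparatus far above their level in stem cells, while the core factors of the pluripotency network, Nanog, Pou5f1 and Sox2, were at background in them. Myh6, the alpha myosin heavy chain, stood at 14.95 ± 0.12 in CMp and 5.66 ± 0.17 in mES, a 628-fold difference (adjusted p = 2.08e-11, limma). Nanog, a core transcription factor of pluripotency, was at 12.68 ± 0.18 in mES and was detected on none of the CMp arrays, which put it at least 211-fold lower there (adjusted p = 4.69e-11). Transcripts of fatty acid oxidation were higher in CMp, and those of ribosome production were lower.

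Of 26 pluripotency genes measured, 24 fell in CMp and 2 did not pass the test, with a median log2 change of -5.32 (-5.23), the value in brackets here and below setting members at their bound where the tested probe was undetected on every array of a group (camera, adjusted p = 5.67e-12). Dppa5a, a marker of pluripotent cells, fell 852-fold and Dppa4 at least 212-fold. Pou5f1 and Sox2, which act with Nanog, were at least 169-fold and 45.5-fold lower (adjusted p = 9.26e-11 and adjusted p = 1.23e-09). Trh, which encodes thyrotropin-releasing hormone, and Ooep, an oocyte-expressed gene, were also among the 5 largest decreases, at least 267-fold and 194-fold. Early lineage markers split evenly, with 4 of 8 higher and 4 lower (median 0.51 (0.68), adjusted p = 0.652). In that list Gata6, a cardiac and endoderm factor, rose 114-fold and Sox7 67.1-fold, while Otx2, an epiblast and forebrain factor, fell at least 37-fold.

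Cell cycle and DNA replication genes fell in 28 of 29 cases (median log2 change -2.48, adjusted p = 4.63e-08, and adjusted p = 0.0536 with an estimated correlation). Mcm3, part of the replicative helicase, changed by -3.63 ± 0.19 (adjusted p = 2.77e-08), the checkpoint kinase gene Bub1b by -3.42 ± 0.27 and Top2a, a topoisomerase of dividing cells, by -2.57 ± 0.32. Plk1, a mitotic kinase, was the exception and rose by 1.78 ± 0.18 (adjusted p = 4.39e-06). All 14 ribosome biogenesis genes fell (median -2.21, adjusted p = 2.23e-05), among them the nucleolar factors Nop56 (-3.15 ± 0.24) and Gnl3 (-2.99 ± 0.22). Of 26 regulators of chromatin and DNA methylation 21 fell and 3 rose (median -1.30 (-1.18), adjusted p = 0.000933, and adjusted p = 0.0705 with an estimated correlation). The de novo DNA methyltransferase gene Dnmt3b fell 42.8-fold (adjusted p = 2.19e-09) and its cofactor Dnmt3l at least 175-fold, while Smarcd3, a cardiac subunit of a chromatin remodelling complex, rose by 2.64 ± 0.20, and Hdac5 and Hdac9 were the other members that rose, the call of Hdac9 being lost over the arrays of CMp replicate 1 with CMa replicates 1 and 2.

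Sarcomere genes rose in 24 of 25 cases, with a median log2 change of 7.24 (7.19) (adjusted p = 1.31e-12). Myl3, the ventricular essential myosin light chain, was 1150-fold higher (adjusted p = 2.17e-11), and Myl2 and the troponin C gene Tnnc1 were 882-fold and 847-fold higher, and as all 3 stood close to the highest level on the arrays in CMp, these folds can be compressed. Both troponin I genes were higher, Tnni1, the isoform of slow skeletal and fetal heart muscle, by 7.19 ± 0.20 and Tnni3, the cardiac isoform, at least 59.2-fold. Actc1, the cardiac actin gene, differed by 8.88 ± 0.37, Acta1, the skeletal one, by 2.79 ± 0.24, and Myh7, the beta myosin heavy chain, by at least 8.85-fold (adjusted p = 9.11e-06), its fitted log2 change of 3.77 being 3.13 without CMp replicate 1. All 15 calcium handling genes rose (median 4.97 (4.38), adjusted p = 1.46e-07, and adjusted p = 0.0536 with an estimated correlation), including the ryanodine receptor Ryr2 (7.32 ± 0.23), the calcium pump Atp2a2 (5.86 ± 0.17), its inhibitor Pln (at least 118-fold) and the sodium-calcium exchanger Slc8a1 (at least 154-fold). Ion channel and gap junction genes rose in 10 of 14 cases and fell in 2 (median 1.95 (1.48), adjusted p = 0.00181, and adjusted p = 0.0536 with an estimated correlation), with Kcne1, a potassium channel subunit, at least 94.2-fold higher. The members that fell were Hcn2 and Kcnj3, calls lost with the authors' normalized matrix, that of Kcnj3 also without mES replicate 2, CMp replicate 2 or CMp replicate 3. All 13 cardiac transcription factors rose (median 3.92 (3.83), adjusted p = 6.14e-07, and adjusted p = 0.0565 with an estimated correlation), Nkx2-5 by 4.63 ± 0.35, Gata4 at least 2.42-fold and Mef2c at least 53.2-fold. Of 12 genes of the fetal cardiac programme 11 rose (median 4.92, adjusted p = 9.76e-06), with the natriuretic peptide genes Nppa and Nppb at least 523-fold and 163-fold higher. Of the genes above, Myl3, Ryr2, Nkx2-5 and Tnni1, and Cpt1b below, were detected by the tested probe on 1 of 3 mES arrays, and Myl2 and Sox7 on 2. The weakest kept probes of Ryr2, Atp2a2, Kcne1 and Mef2c gave log2 changes of 0.67, -0.03, 0.86 and 1.46, and that of Lpl, named below, 0.44.

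Genes of fatty acid oxidation rose in 23 of 25 cases (median 2.97, adjusted p = 8.71e-09), including Cpt1b, the muscle carnitine palmitoyltransferase (6.89 ± 0.27, adjusted p = 2.86e-09), and lipoprotein lipase, Lpl (6.50 ± 0.23). Of 42 oxidative phosphorylation genes 38 rose and none fell (median 1.50, adjusted p = 2.08e-09, and adjusted p = 0.0536 with an estimated correlation). The largest of these changes were in Cox6a2 and Cox8b, muscle isoforms of cytochrome c oxidase subunits, at least 868-fold and 415-fold, and in Cox7a1 (4.59 ± 0.19). Tricarboxylic acid (TCA) cycle genes rose in 12 of 14 cases and 1 fell (median 1.58, adjusted p = 0.000509, and adjusted p = 0.0869 with an estimated correlation). Idh2 and Ogdh rose by 3.46 ± 0.27 and 3.34 ± 0.24, and the member that fell was Idh3b, whose 2 kept probes moved apart, by -0.57 and 1.35, and averaged 0.39. Glycolysis genes went both ways, 5 up and 7 down of 16, with a median of -0.19 and a mean of 0.48 (adjusted p = 0.926). The muscle isoforms Pgam2 and Eno3 rose by 7.28 ± 0.18 and 5.60 ± 0.18, and Pgam1, the non-muscle counterpart of Pgam2, changed by -2.79 ± 0.22. Of 9 metabolic transcription regulators 5 rose and 2 fell (median 0.93 (0.48), adjusted p = 0.105), Ppargc1a, a coactivator of mitochondrial biogenesis, at least 75.6-fold. Imprinted growth genes rose in 9 of 10 cases (median 2.46, adjusted p = 0.000933, and adjusted p = 0.0536 with an estimated correlation), Igf2 by 4.47 ± 0.21 and Dlk1 by 3.49 ± 0.20. Circadian clock genes rose in 7 of 10 cases (median 1.54, adjusted p = 0.0137, and adjusted p = 0.107 with an estimated correlation), Per2 by 2.80 ± 0.27. Immediate early and stress genes rose in 12 of 14 and 1 fell (median 3.89, adjusted p = 1.4e-05). Hspa1a, an inducible heat shock protein gene, rose 284-fold and Atf3 140-fold, and the member that fell was Socs3 (-0.85 ± 0.33, adjusted p = 0.0377), a call lost without mES replicate 1 or 3, CMp replicate 2 or 3, or CMa replicate 2.

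Markers of other heart cells rose beside those of cardiomyocytes. The fibroblast markers did so in 18 of 19 cases (median 4.57 (4.09), adjusted p = 7.96e-09), decorin, Dcn, at least 380-fold and the collagen gene Col1a1 at least 91.5-fold, although the authors' normalized matrix under its own probe identifiers gave -0.02 for the log2 change of Col1a1. All 16 endothelial markers rose (median 4.45 (4.27), adjusted p = 3.06e-08, and adjusted p = 0.082 with an estimated correlation), Cldn5 181-fold and Emcn at least 131-fold. Smooth muscle and pericyte markers rose in 8 of 9 cases (median 2.35 (1.86), adjusted p = 0.000933, and adjusted p = 0.0536 with an estimated correlation), and all 4 epicardial and mesothelial markers rose (median 2.50 (1.97), adjusted p = 0.00672, and adjusted p = 0.0536 with an estimated correlation). Leukocyte and macrophage markers rose in 11 of 14 and 1 fell (median 1.58 (1.07), adjusted p = 0.00268, and adjusted p = 0.184 with an estimated correlation), Cd14 at least 13.4-fold. Of 4 erythroid markers 3 rose (median 3.08, adjusted p = 0.0422, and adjusted p = 0.132 with an estimated correlation), the alpha globin gene Hba-a1 at least 1060-fold, and without CMp replicate 1 the list gave adjusted p = 0.0513, with the authors' normalized matrix 0.0583 and without the detection filter 0.0735. The beta globin genes Hbb-bs and Hbb-bt, near-identical copies whose signals a probe may share, were at least 1000-fold and 971-fold higher. All 8 atrial markers rose (median 4.12 (3.82), adjusted p = 0.000668, and adjusted p = 0.0773 with an estimated correlation), as did 5 of 6 ventricular markers (median 3.59 (3.40), adjusted p = 0.000715, and adjusted p = 0.0536 with an estimated correlation). The sex-linked genes, with a median of 0.18 (-0.09) and adjusted p = 0.926, moved apart, Xist, transcribed from the inactive X chromosome, at least 66-fold higher in CMp and the Y-linked Eif2s3y at least 39.6-fold lower.

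Across all 10800 genes tested, 8012 (74.2%) differed between CMp and mES, 3826 higher and 4186 lower in CMp, of which 5709 differed at least 2-fold (2811 higher, 2898 lower). In 8403 genes (77.8%, against 10% by chance) the groups did not overlap. Of the 27 lists, 23 were called by camera, 19 higher and 4 lower, and 7 of them also with an estimated correlation. Adjusted over the list alone, member counts were those given above in every list except fatty acid oxidation, in which 24 rose. With arrays scaled to a common median in place of quantile normalization, the median of all genes moved from -0.09 to -0.59, so that changes are relative to that shift, and higher calls went from 47.8% to 34.6% of 8546 calls. The count of genes changed at least 2-fold was 2687 with the authors' normalized matrix and 3703 without background correction, and 3770 genes passed a test against 2-fold itself.

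The second comparison asked how adult cardiomyocytes differ from stem cells. The pattern of the neonatal cells recurred, with sarcomere and fatty acid oxidation transcripts high and pluripotency and cell cycle transcripts low, and the cell cycle genes were mostly at or near background. Csrp3, a Z-disc protein of striated muscle, was at 14.73 ± 0.11 in CMa and undetected on the mES arrays, at least 859-fold higher (adjusted p = 3.44e-12). Cdc20, an activator of the anaphase-promoting complex, fell 94.1-fold, from 12.08 ± 0.06 in mES to 5.52 ± 0.45 in CMa (adjusted p = 1.36e-09). Genes with imprinted expression did not show the shared rise seen in CMp, where the camera call was lost with an estimated correlation (adjusted p = 0.0536).

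All 26 pluripotency genes fell in CMa (median -5.67 (-5.03), adjusted p = 1.07e-11), Dppa5a 937-fold, Nanog at least 150-fold, Pou5f1 at least 120-fold and Sox2 at least 32.4-fold. The glucose transporter gene Slc2a3 was another of the 5 largest decreases (-8.35 ± 0.35, adjusted p = 3.27e-09). All 29 cell cycle genes fell (median -4.78 (-4.72), adjusted p = 1.07e-11), Bub1b by 90.3-fold, the helicase gene Mcm5 by 67.4-fold and Top2a by 56-fold. Ribosome biogenesis genes fell in 13 of 14 cases (median -2.45, adjusted p = 6.17e-05), Nop56 by 21.2-fold. Of 26 chromatin and DNA methylation regulators 21 fell and 3 rose (median -1.66 (-1.56), adjusted p = 0.000359, and adjusted p = 0.0867 with an estimated correlation), with Dnmt3b down 99.6-fold and Uhrf1, a partner of maintenance methylation, down 59.1-fold. The second kept probes of Dnmt3b and Uhrf1 fell less, with log2 changes of -2.41 and -1.14. Early lineage markers gave 3 higher and 4 lower of 8, with a median of -0.09 and a mean of 0.55 (adjusted p = 0.951).

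Sarcomere genes rose in 23 of 25 cases (median 7.83, adjusted p = 3.37e-10). Myh6 was 627-fold higher, Myl3 1020-fold, Actc1 467-fold and Acta1 76-fold, and Tcap, the titin cap protein, at least 756-fold. The tropomyosin gene Tpm1 changed by -1.41 ± 0.16 (adjusted p = 8.65e-06). Tnni3 was at least 105-fold higher, whereas Tnni1 was near background in both groups (4.52 ± 0.23 in CMa, 4.74 ± 0.36 in mES, adjusted p = 0.347), its log2 difference of -0.22 turning with cyclic loess to 0.78, called higher in CMa (adjusted p = 0.0062). Myh7 was at least 3.37-fold higher (adjusted p = 0.000294), a call lost with the authors' normalized matrix (adjusted p = 0.127). All 15 calcium handling genes rose (median 6.08 (5.64), adjusted p = 1.46e-07, and adjusted p = 0.0699 with an estimated correlation), Ryr2 298-fold, Atp2a2 60.8-fold and Pln at least 305-fold. Ion channel genes rose in 13 of 14 cases with 1 lower, Cacna1h, a call lost with the authors' normalized matrix (median 2.32 (1.94), adjusted p = 0.000155), and the 13 cardiac transcription factors all rose (median 3.79, adjusted p = 4.75e-06, and adjusted p = 0.0959 with an estimated correlation), Nkx2-5 by 4.89 ± 0.35 and Gata4 at least 2.73-fold. Fetal cardiac genes rose in 8 of 12 and fell in 3 (median 2.30 (1.99), adjusted p = 0.0384, and adjusted p = 0.146 with an estimated correlation), Nppa and Nppb being at least 558-fold and 498-fold higher and Igf2, Cacna1h and Tagln lower. The fetal list gave adjusted p = 0.053 with the mean of a gene's probes. By the tested probe alone, Myl3, Ryr2, Nkx2-5, Cpt1b and Nr1d1 were detected on 1 of 3 mES arrays, Bub1b, Cdc20, Top2a and Slc2a3 on 1 of 3 CMa arrays, and Dppa5a and Fn1 on 2 of 3 CMa arrays. The weakest kept probes of Atp2a2 and Ryr2 gave log2 changes of 0.35 and 2.5.

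Fatty acid oxidation genes rose in 24 of 25 cases (median 3.71, adjusted p = 1.11e-09), Cpt1b 200-fold and Lpl 225-fold. Oxidative phosphorylation genes rose in 39 of 42 with 1 lower, Uqcrq (median 2.04, adjusted p = 5.59e-11, and adjusted p = 0.0657 with an estimated correlation), and Cox7a1 was 98.1-fold higher. TCA cycle genes rose in 13 of 14 with 1 lower, Idh3b, whose 2 kept probes moved by -1.53 and 0.75 (median 2.17, adjusted p = 0.000132, and adjusted p = 0.0959 with an estimated correlation). Glycolysis genes split 6 up and 6 down of 16 (median 0.09, adjusted p = 0.492), with the glucose transporter Slc2a1 down 19-fold and Pgam2 up 256-fold. Metabolic transcription regulators gave 5 higher and 3 lower of 9 (median 2.33 (1.88), adjusted p = 0.0645), the nuclear receptor Esrrg at least 24.8-fold higher. Imprinted growth genes gave 2 higher and 6 lower of 10 (median -0.91, adjusted p = 0.218), Igf2 falling 1.99-fold (adjusted p = 0.00111) and Dlk1 at least 7.79-fold. Clock genes rose in 7 of 10 (median 1.61, adjusted p = 0.0166, and adjusted p = 0.138 with an estimated correlation), Nr1d1 by 2.94 ± 0.30. Immediate early and stress genes rose in 11 of 14 and fell in 2, Socs3 and, lost with the authors' normalized matrix, Myc (median 2.06 (1.94), adjusted p = 0.005, and adjusted p = 0.0885 with an estimated correlation), Hspa1a by 53.5-fold.

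Among markers of other cells, all 16 endothelial genes were higher in CMa than in mES (median 4.08 (3.84), adjusted p = 1.59e-06, and adjusted p = 0.138 with an estimated correlation), as were 7 of 9 smooth muscle and pericyte genes, Tagln being lower (median 1.98 (1.47), adjusted p = 0.00838, and adjusted p = 0.0998 with an estimated correlation). Fibroblast markers were higher in 10 of 19 and lower in 3, Fn1, Fstl1 and Thy1 (median 1.05 (0.56), adjusted p = 0.0469, and adjusted p = 0.328 with an estimated correlation), the Thy1 call being lost without mES replicate 3 or CMa replicate 1. Dcn was at least 139-fold higher and the fibronectin gene Fn1 21.6-fold lower, while their weakest kept probes gave log2 changes of 0.05 and -0.81. The camera call of the fibroblast list was lost without mES replicate 1, CMp replicate 1 or CMa replicate 2, at adjusted p = 0.0512, 0.0506 and 0.0623, and with the authors' normalized matrix, at 0.122. Leukocyte markers (9 higher, 1 lower of 14, adjusted p = 0.0686), erythroid markers (2 of 4 higher, adjusted p = 0.353) and epicardial markers (1 of 4 higher, adjusted p = 0.76) were not called as lists, with medians of 0.99 (0.45), 0.57 and 0.02 (0.00). Atrial markers rose in 7 of 8 (median 2.35 (2.04), adjusted p = 0.0223, and adjusted p = 0.209 with an estimated correlation) and ventricular markers in 6 of 6 (median 3.66, adjusted p = 0.000823, and adjusted p = 0.0835 with an estimated correlation). The atrial call was lost with the authors' normalized matrix (adjusted p = 0.079). Of the sex-linked genes (median 0.18, mean -0.84, adjusted p = 0.974), Eif2s3y was at least 28.2-fold lower and Kdm5d at least 3.01-fold higher in CMa.

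In all, 8315 of 10800 genes (77%) differed between CMa and mES, 3970 higher and 4345 lower, with 6234 changed at least 2-fold (3060 higher, 3174 lower). The groups did not overlap in 8653 genes (80.1%, against 10% by chance). Camera called 19 of the 27 lists, 15 higher and 4 lower, 6 of them also with an estimated correlation. Adjusted over the list alone, member counts were those given above except for 6 in place of 5 metabolic regulators higher. Median scaling moved the median of all genes from -0.07 to -0.79, to which changes are relative, and the share of higher calls from 47.7% to 31% of 8707 calls. The authors' normalized matrix gave 3170 genes changed at least 2-fold, and 4346 passed a test against 2-fold itself.

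Both cardiomyocyte groups departed from stem cells largely in the same direction. Of the genes called, 2927 were higher in both CMp and CMa than in mES, Myh6, Ryr2 and Cox6a2 among them, and 3478 were lower in both, Nanog, Dnmt3b and Nop56 among them. Both comparisons use the same mES arrays and so share their chance deviations. Independent lists of these sizes would share 1406 and 1684 genes. Groups with no change, simulated against the same mES arrays, shared at most 1 gene in either direction, with means of 0.015 and 0.005 over 200 simulated data sets. Groups without change give few calls by design, so this does not measure how the shared arrays affect the overlap of changed genes. Genes called in opposite directions numbered 183 (higher in CMp and lower in CMa) and 140 (the reverse).

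**Figure D1:**
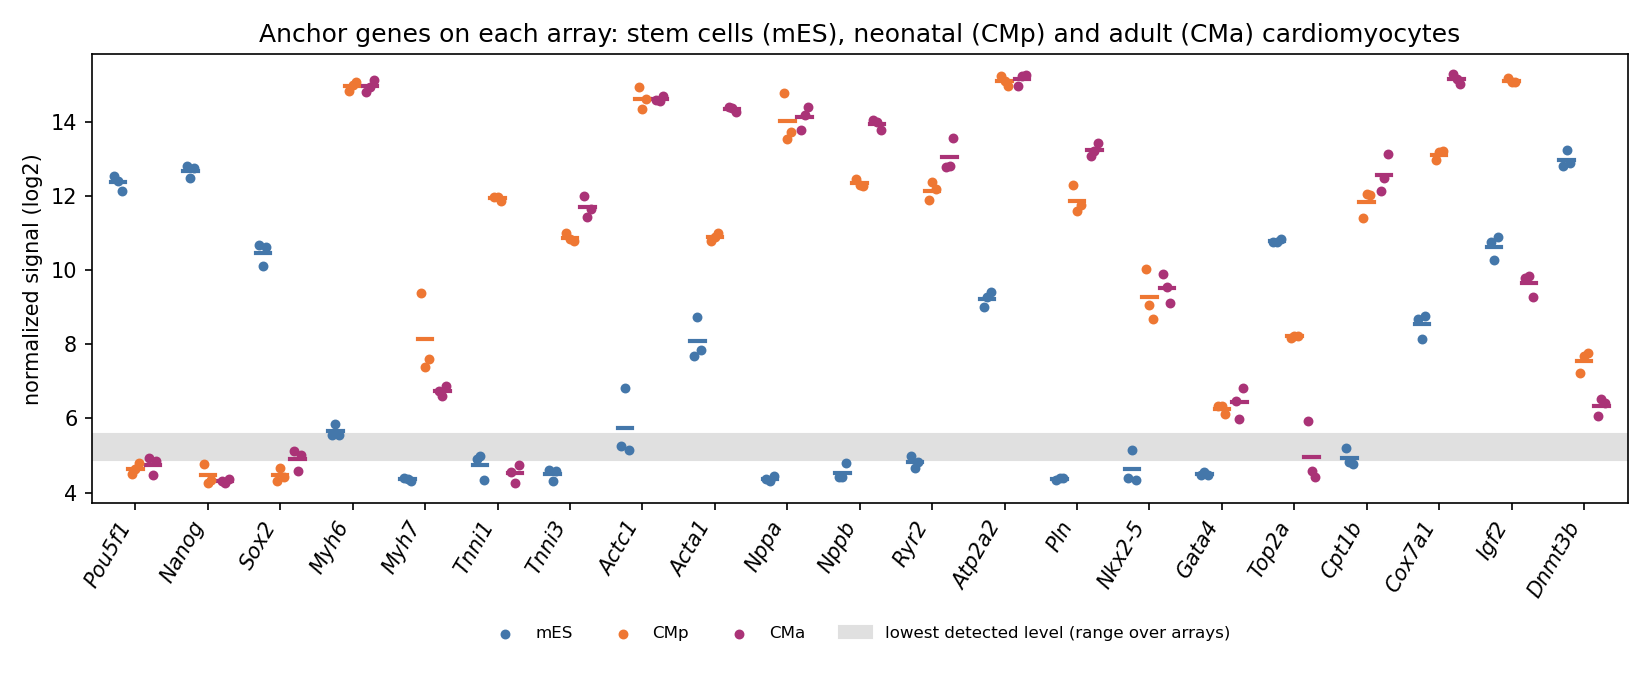
Log2 levels of the anchor genes on each array (points) with group means (bars) for mES, CMp and CMa, the grey band marking the lowest detected levels. Myh6 stood at 5.66 ± 0.17 in mES, 14.95 ± 0.12 in CMp and 14.95 ± 0.16 in CMa, and Tnni1 was high in CMp alone (11.93 ± 0.06).

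The third comparison set adult against neonatal cardiomyocytes, asking which transcripts differ between the 2 stages. Cell cycle, imprinted growth and early response genes and fibroblast markers were lower in the adult preparations, calls lost at adjusted p = 0.0552 each with an estimated correlation. Oxidative phosphorylation genes were higher, a call lost at adjusted p = 0.208 with an estimated correlation. The measured levels of Myh6, Actc1 and the core pluripotency factors stood near the neonatal ones. Markers of several other heart cells fell too, so changes within cardiomyocytes were not told apart from a different mix of cells. Tnni1, the slow and fetal troponin I, fell at least 89.7-fold, from 11.93 ± 0.06 in CMp to undetected in CMa (adjusted p = 2.59e-09), as did Dlk1, an imprinted regulator of growth, at least 87.3-fold. Igf2, the fetal insulin-like growth factor, fell 44.2-fold, from 15.10 ± 0.07 to 9.64 ± 0.32 (adjusted p = 2.33e-08). The largest increases were in Ces1d, a carboxylesterase (118-fold), 2310002L09Rik (49.4-fold), Art1 (at least 53.9-fold), Scn4b, a sodium channel subunit (40.1-fold), and Bdh1, a ketone body enzyme (at least 38.8-fold). The second kept probes of 2310002L09Rik and Scn4b moved less, with log2 changes of 0.98 and 0.50.

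Cell cycle and DNA replication genes fell in 27 of 29 cases (median -2.32 (-2.08), adjusted p = 1.38e-13), which gave adjusted p = 0.0552 with an estimated correlation. Cdc20 changed by -3.57 ± 0.24, the survivin gene Birc5 by -3.56 ± 0.16 and Top2a by -3.24 ± 0.32. Imprinted growth genes fell in 9 of 10 cases (median -2.36, adjusted p = 1.7e-05, and adjusted p = 0.0552 with an estimated correlation), Peg3 among them (-3.96 ± 0.27). Immediate early and stress genes fell in 12 of 14 cases (median -1.91 (-1.82), adjusted p = 7.59e-05, and adjusted p = 0.0552 with an estimated correlation), including Fosb, a subunit of the AP-1 factor (-4.53 ± 0.49), and Socs3 (-2.79 ± 0.33). In the same arrays all 19 fibroblast markers fell (median -3.23, adjusted p = 2.55e-13), at adjusted p = 0.0552 with an estimated correlation. The collagen genes Col1a1 and Col5a1 fell by 47.8-fold and 28.5-fold (adjusted p = 2.4e-08 and adjusted p = 1.21e-07), the Col1a1 call being lost with the authors' matrix under its own probe identifiers, and Lox, a collagen cross-linking enzyme, at least 12.9-fold. Chromatin and DNA methylation regulators fell in 10 of 26 and rose in 2 (median -0.43, adjusted p = 0.0506), short of the threshold in the fit used here, with adjusted p = 0.287 with an estimated correlation, while 15 of 23 other alternatives called it. Uhrf1 (-3.31 ± 0.22), Ezh2, a histone methyltransferase of the Polycomb group (-2.24 ± 0.19), and Dnmt3b (-1.22 ± 0.20) fell, while Cbx7, another Polycomb gene, was at least 2.74-fold higher. The second kept probes of Uhrf1, Ezh2 and Dnmt3b moved less, by -0.03, -0.52 and -0.07. Ribosome biogenesis genes gave 2 higher and 5 lower of 14 (median -0.42, adjusted p = 0.2), Nop58 changing by -1.84 ± 0.16.

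Oxidative phosphorylation genes rose in 32 of 42 cases (median 0.62, adjusted p = 2.55e-06, and adjusted p = 0.208 with an estimated correlation). Cox7a1 rose by 2.03 ± 0.19 (adjusted p = 7.88e-06) and Ndufb3, a complex I subunit, by 1.49 ± 0.17, and Uqcrq, a complex III subunit, was the member that fell (-2.10 ± 0.29). Fatty acid oxidation genes rose in 17 of 25 and 1 fell (median 0.95, adjusted p = 0.000501, and adjusted p = 0.208 with an estimated correlation), the transporter Slc27a1 rising by 1.87 ± 0.22 and Decr1 by 1.53 ± 0.19, with Hadha falling (-1.35 ± 0.19). Cpt1b rose by 0.76 ± 0.27 (adjusted p = 0.0357), a call lost without mES replicate 2 (adjusted p = 0.0502), CMp replicate 1 (0.0985), CMa replicate 2 (0.0635) or CMa replicate 3 (0.133). TCA cycle genes rose in 11 of 14 and 1 fell, Idh3b (median 0.61, adjusted p = 0.00792, and adjusted p = 0.269 with an estimated correlation). Dlat, of the pyruvate dehydrogenase complex, rose by 2.30 ± 0.22. Metabolic transcription regulators rose in 4 of 9 and 1 fell, Nrf1 (median 0.40, adjusted p = 0.0679), a call lost without CMp replicate 2, CMp replicate 3 or CMa replicate 2, with Esrrg higher by 2.17 ± 0.21 and the lipid-sensing receptor Ppara by 1.40 ± 0.23. Glycolysis genes rose in 6 of 16 and fell in 2, the glucose transporter Slc2a1 and Aldoc (median 0.31, adjusted p = 0.181), the list being called with median scaling (adjusted p = 0.0275). Calcium handling genes rose in 8 of 15 cases (median 0.90, adjusted p = 0.00823, and adjusted p = 0.287 with an estimated correlation), Pln by 1.37 ± 0.20, Hrc, a calcium-binding protein of the sarcoplasmic reticulum, by 2.26 ± 0.22 and Ryr2 by 0.90 ± 0.23. Without the probes whose values differed between the authors' tables, that list gave adjusted p = 0.105.

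Sarcomere genes were split, 10 up and 5 down of 25, and the list was not called (median 0.46, mean 0.01, adjusted p = 0.2), although it was with median scaling (adjusted p = 0.00964). Tnni3 and Acta1 rose by 0.82 ± 0.18 and 3.46 ± 0.24, the Tnni3 call being lost when CMp replicate 1 was set against CMa replicates 1 and 2 alone, and Tnni1, Tpm1 (-1.55 ± 0.16), Myl7 (-3.14 ± 0.73), Myl4 (-2.68 ± 0.61) and Myh7 (-1.39 ± 0.41) fell, the Myh7 call being lost with the authors' normalized matrix (adjusted p = 0.0687). Without CMp replicate 1, in which all 3 were highest, the log2 changes of Myl7, Myl4 and Myh7 were -2.16, -2.02 and -0.77, and that of Myl7 was -2.53 without CMa replicate 1. Myh6 was at 14.95 ± 0.16 in CMa and 14.95 ± 0.12 in CMp, a log2 difference of 0.00 ± 0.16 (adjusted p = 0.991), and like Actc1 and Atp2a2 it stood close to the highest level on the arrays, where a difference can be compressed. Differences in Actc1 (-0.01 ± 0.37), Atp2a2 (0.06 ± 0.17), Nkx2-5 (0.26 ± 0.35), Gata4 (0.17 ± 0.21) and Nppa (0.09 ± 0.29) did not pass the test, although Nppa was called lower in CMa, at -0.74 (adjusted p = 0.0366), when CMp replicate 1 was set against CMa replicates 1 and 2 alone. Cardiac transcription factors gave 0 higher and 3 lower of 13 (median -0.03, adjusted p = 0.487), among the latter the ventricular repressor Hey2 (-2.01 ± 0.20). Fetal cardiac genes fell in 8 of 12 and rose in 3, Acta1, Ankrd1 (1.41 ± 0.18) and Nppb (1.61 ± 0.17), and the list was not called (median -1.98 (-1.90), and -1.39 without CMp replicate 1, adjusted p = 0.0728). Ion channel genes rose in 6 and fell in 3 of 14 (median 0.15, adjusted p = 0.346), the potassium channel gene Kcnd2 rising by 3.47 ± 0.18, Hcn2 by 3.18 ± 0.21, Kcne1 changing by -2.72 ± 0.16 and Cacna1h at least 5.33-fold. Pluripotency genes were mostly near background in both groups (20 of 26 not called, median -0.02 (0.00), adjusted p = 0.563). Nanog stood at 4.31 ± 0.05 in CMa and 4.46 ± 0.27 in CMp, Pou5f1 at 4.74 ± 0.25 and 4.64 ± 0.14, and Sox2 at 4.91 ± 0.28 and 4.47 ± 0.18, undetected throughout. Klf5 fell at least 13-fold and Klf4 changed by -1.88 ± 0.36, and Esrrb, which also acts in oxidative muscle, rose by 1.92 ± 0.17. Early lineage markers fell in 4 of 8 (median -0.55 (-0.44), adjusted p = 0.0677). Clock genes gave 2 higher and 3 lower of 10 (median 0.06, adjusted p = 0.971), Dbp rising by 1.94 ± 0.25 and Per2 changing by -1.49 ± 0.27.

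Of the markers of other cells, the 4 epicardial and mesothelial genes all fell (median -2.52 (-1.50), adjusted p = 0.00151, and adjusted p = 0.0614 with an estimated correlation), including Upk3b (-3.12 ± 0.21). Endothelial markers fell in 10 of 16 and 1 rose, Ly6c1 (median -0.92, adjusted p = 0.00853, and adjusted p = 0.417 with an estimated correlation). Cldn5, a tight junction protein (-3.44 ± 0.29), and the von Willebrand factor gene Vwf (-2.44 ± 0.27) fell. Leukocyte markers fell in 10 of 14 and 2 rose, Cd74 and H2-Ab1, whose calls were lost with the authors' matrix under its own identifiers and with median scaling, in that order (median -0.91 (-0.77), adjusted p = 0.0266, and adjusted p = 0.38 with an estimated correlation), and erythroid markers fell in 3 of 4 (median -2.35 (-2.05), adjusted p = 0.0316, and adjusted p = 0.208 with an estimated correlation), Hba-a1 among them (-3.11 ± 0.25). Without CMp replicate 1 the leukocyte list gave adjusted p = 0.0873 and the erythroid list 0.0521. The endothelial list gave adjusted p = 0.173 when CMp replicate 1 was set against CMa replicates 1 and 2 alone, and the TCA cycle list 0.0665. The chemokine gene Ccl4 and the adhesion gene Selp were among the 5 largest decreases, at least 90.9-fold and 66.7-fold. Smooth muscle and pericyte markers gave 1 higher and 2 lower of 9 (median -0.25, adjusted p = 0.372), Acta2 changing by -2.58 ± 0.23. By the tested probe alone, Scn4b was detected on 1 of 3 CMp arrays, Cdc20 and Top2a on 1 of 3 CMa arrays, and Col1a1, Dkk3 and Upk3b on 2 of 3 CMa arrays. Atrial markers fell in 4 of 8 (median -1.06, adjusted p = 0.0611), including Dkk3 (-4.48 ± 0.31), and ventricular markers gave 1 higher and 1 lower of 6 (median -0.12, mean 0.15, adjusted p = 0.971). Of the sex-linked genes (median 0.35, mean -1.16, adjusted p = 0.975), Xist was at least 47.8-fold lower in CMa, and Kdm5d rose by 1.31 ± 0.20.

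Between CMa and CMp, 5651 of 10800 genes (52.3%) differed, 2856 higher and 2795 lower in CMa, with 3143 changed at least 2-fold (1506 higher, 1637 lower). The groups did not overlap in 6018 genes (55.7%, against 10% by chance). Camera called 12 of 27 lists, 4 higher and 8 lower, and with an estimated correlation it called 0, with 27 lists tested, although cell cycle, fibroblast, imprinted and early response genes each gave adjusted p = 0.0552 there. The epicardial call was lost there too, although the estimate for that list, -0.15, lay below the preset correlation. Fry asks whether members change at all, not whether they change more than other genes. It gave unadjusted p = 5.24e-08 for cell cycle, 1.55e-08 for fibroblast, 3.92e-08 for imprinted and 1.15e-06 for early response genes. Early lineage markers, which camera did not call, gave 5.8e-06 by fry, so a low value there does not replace a camera call. Adjusted over the list alone, member counts were those given above except for 11 sarcomere and 34 oxidative phosphorylation genes higher. Age and heart region differ together between these groups, the labels giving heart as the source of CMp and left ventricle as that of CMa. Xist and the Y-linked Kdm5d differ as well, and the labels give no sex. The Y-linked Eif2s3y did not differ (-0.04, adjusted p = 0.874, limma), but it was at background in both groups and so cannot tell. Markers of fibroblasts and other heart cells also fell. The comparison cannot part age, region, sex and the mix of cells in the preparations. Median scaling moved the median of all genes from 0.01 to -0.20, to which changes are relative, and higher calls from 50.5% to 35% of 5668 calls. The count of genes changed at least 2-fold was 1249 with the authors' normalized matrix and 1764 without background correction, and 1301 genes passed a test against 2-fold itself.

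**Figure D2:**
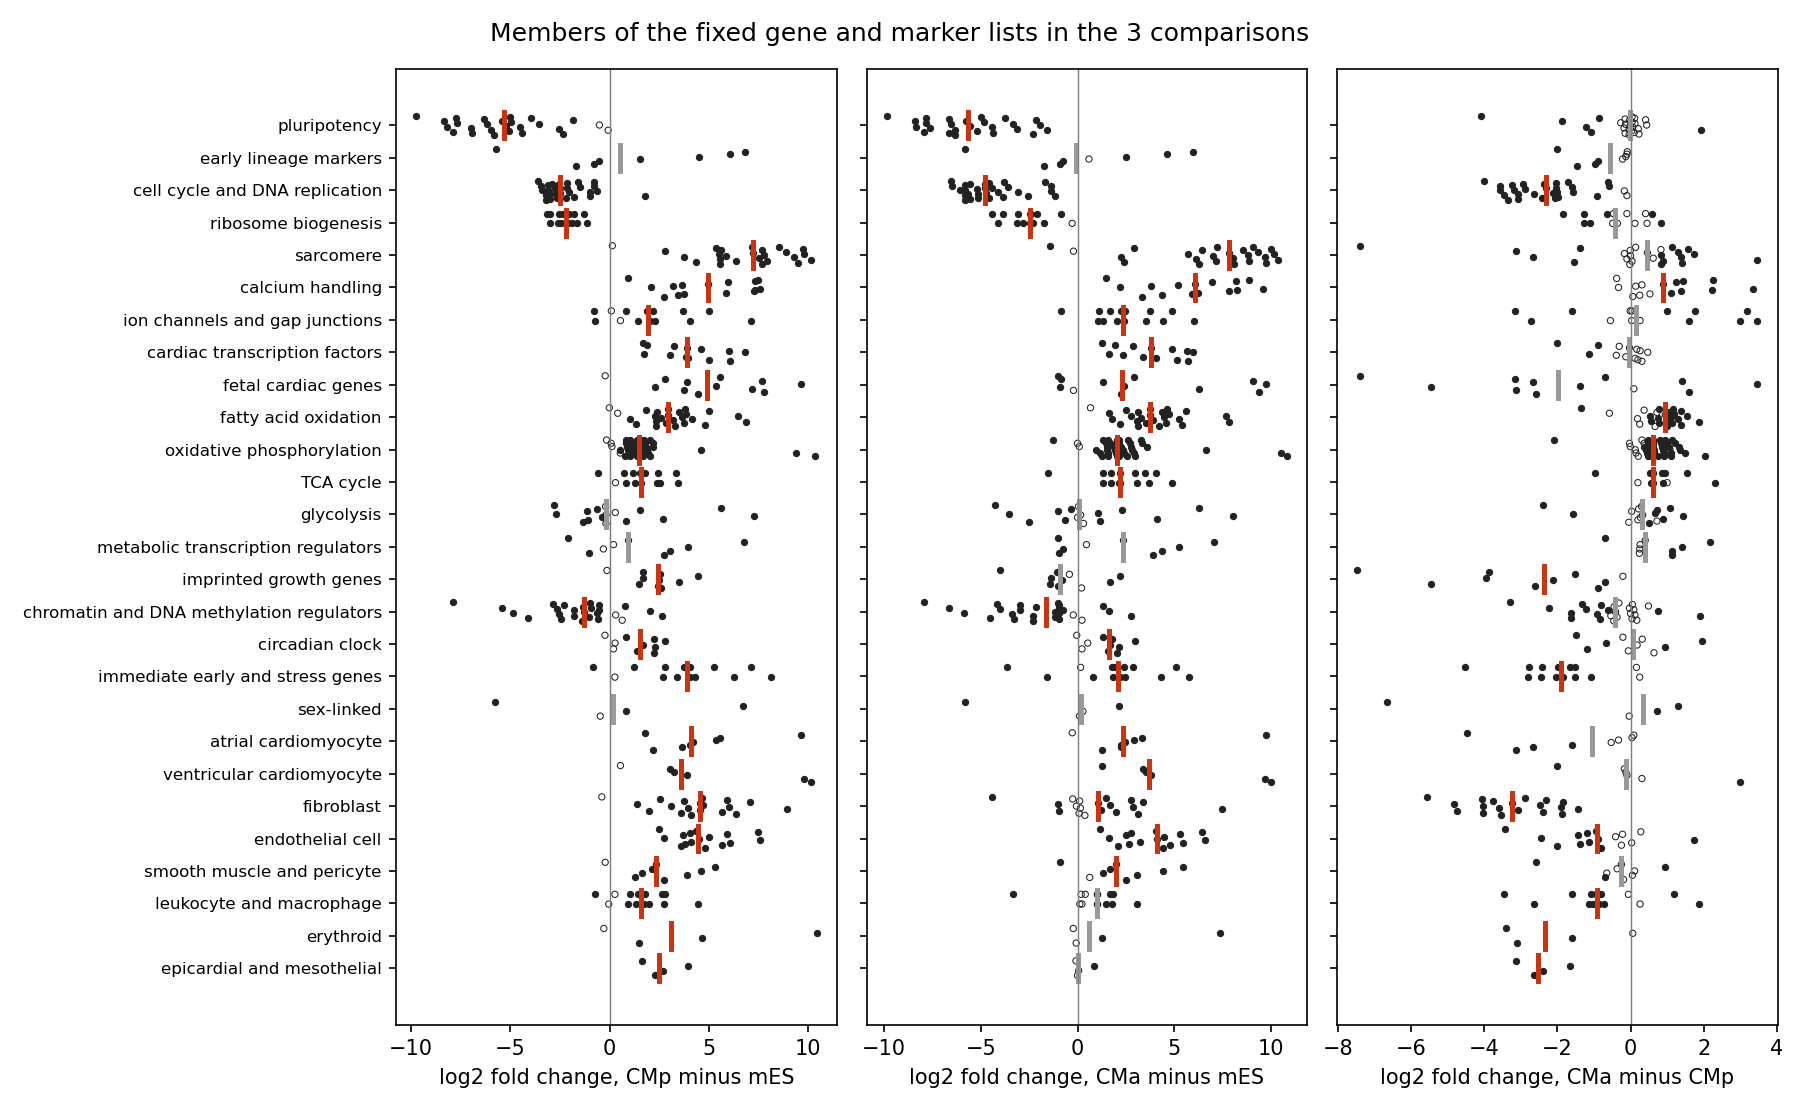
Log2 change of every list member (points, filled where called) in the 3 comparisons, with list medians as bars, red where camera called the list and grey where not. Cell cycle and fibroblast medians were -2.32 and -3.23 in CMa against CMp, and the sarcomere median was 7.24 in CMp against mES.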

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

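The tests of the difference between replicates described in this part were chosen only after it was seen.

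Probes without a single gene symbol lay outside the gene results and carried a signal no comparison above reports. Of 2745 such probes that passed the detection filter, 2270 (82.7%) differed among the 3 groups by the F-test, and 1260 were detected on all 9 arrays. At least 2-fold changes were found in 1355 of them for CMp against mES, 1497 for CMa against mES and 736 for CMa against CMp.

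CMp replicate 1 stood apart from the other CMp arrays, with 945 genes differing at least 2-fold, against 335 for CMa replicate 3 and 21 for mES replicate 1. Its difference correlated at 0.54 over kept probes with that of the mean of CMa replicates 1 and 2 from CMa replicate 3. By single arrays, deviations from the group mean correlated with those of CMp replicate 1 at 0.35, 0.13 and -0.43 for CMa replicates 1, 2 and 3. CMa replicate 2 thus shared little of the pattern. Purely probe-specific hybridization was argued against. Among 408 genes with a second kept probe whose brightest probe differed at least 2-fold, 80.4% of second probes moved with the brightest. The 95% exact binomial interval, 76.2% to 84.1%, takes genes as independent. For the CMa against CMp change the share was 93.7%, over 1271 genes, so a partly probe-specific difference remains open. Atrial markers were mostly higher in CMp replicate 1 (Sln by 4.66, Myl7 by 3.01, median of 8 markers 0.97), while in CMa replicates 1 and 2 their median difference was -0.24 and ran the other way (correlation across markers -0.92, exact p = 0.00131 from permuting markers, not samples). More atrial tissue remains open, since that result rests on CMa replicate 1, and CMa replicate 2 by itself lay above CMa replicate 3 in 7 of 8 markers (median 0.36, correlation -0.37, p = 0.365). A shared preparation or labelling batch remains open, as none is recorded, and CMa against CMp gave 4516 changed genes over the arrays of that side, and no biological explanation beyond tissue was tested.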

How the results depend on the processing

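Leaving out each array in turn gave 7482 to 8218, 7850 to 8645 and 4843 to 6121 changed genes in CMp against mES, CMa against mES and CMa against CMp, 5579 to 5819, 6128 to 6289 and 3048 to 3519 changed at least 2-fold, and 22 to 23, 18 to 20 and 10 to 16 called lists. It gave 9125 to 9777 genes in the F-test, and 2680 to 3030 higher and 3249 to 3506 lower in both cardiomyocyte groups. No called list turned direction in any alternative, and 102 of 111, 96 of 106 and 84 of 101 called genes among those named kept their call in every alternative fit that held them, the test against 2-fold not being run for single genes here. The fit without probes that differ between the tables held 302 of 328 values of named genes.

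Genes changed at least 2-fold numbered 2687, 3170 and 1249 with the authors' matrix, 2616, 3075 and 1205 with that matrix under its own probe identifiers, and 3703 (CMp against mES) and 1764 (CMa against CMp) without background correction. The cause was not tested. A test against 2-fold called 3770, 4346 and 1301 genes, as it asks for more than a difference from 0. With an estimated correlation 7, 6 and 0 lists were called. Direction turned for Tnni1 in CMa against mES with cyclic loess (0.78, adjusted p = 0.0062), Idh3b in CMp against mES with the mean of probes (0.39), which move apart, Col1a1 in CMp against mES (-0.02) and Thy1 in CMa against mES (0.01) with the matrix under its own identifiers, and Nppa in CMa against CMp over CMp replicate 1 with CMa replicates 1 and 2 (-0.74, adjusted p = 0.0366), and the cause was not tested.

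Of 23 other alternatives, lists not called in the values reported were called in 15 for chromatin regulators, 5 for atrial, 4 for fetal cardiac, 2 for metabolic regulator and 1, without CMp replicate 3, for early lineage genes in CMa against CMp, and in 5 for leukocyte and 3 for metabolic regulator genes in CMa against mES. Median scaling alone called the sarcomere and glycolysis lists in CMa against CMp.

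The replicate block gave 8169, 8437 and 5857 changed genes and 22, 19 and 13 called lists. Under the block the erythroid list in CMp against mES was no longer called (adjusted p = 0.0538) and the chromatin list in CMa against CMp was (adjusted p = 0.0442), and no other call of a list or named gene changed. The numbers were not taken to pair the samples, since only 3 of 9 same-numbered pairs had r over 0.1 (range -0.08 to 0.39), but 6 of 9 arrays correlated best with an array of their own number, which leaves a pairing open. A block for the array chip was not run. Signal over background limits the dimmest genes, and 2, 27 and 13 called genes were undetected in both groups compared.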

Other observations

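The classes of genes described next were chosen only after the values were seen, as were the tests of the fibroblast markers, while the splits of the arrays were planned before the data were examined.

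Some genes did not follow a path from stem cells through neonatal to adult cells. In 769 genes the level was highest in CMp, each difference from mES and from CMa being called and at least 2-fold. Among them were the chemokine genes Cxcl1 and Ccl7, at least 278-fold and 123-fold higher in CMp than in mES and changed by -6.28 and -6.19 on the log2 scale from CMp to CMa, and the elastin gene Eln (at least 156-fold, then -6.05). By the same rule 253 genes were lowest in CMp, including the alkaline phosphatase gene Alpl (log2 changes of -3.55 from mES to CMp and 2.74 from CMp to CMa) and the DNA repair gene Mgmt (-4.02 and 2.73).

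Other genes moved stepwise. In 469 genes levels rose from mES to CMp and again to CMa, among them the mitochondrial creatine kinase gene Ckmt2 (at least 50.1-fold, then a log2 change of 4.20), the muscle ribosomal protein gene Rpl3l (4.25 and 4.29), the insulin-responsive glucose transporter gene Slc2a4 (at least 5.42-fold, then 3.05) and Acta1 (2.79 and 3.46). In 337 genes levels fell at each step, among them the serine and asparagine synthesis genes Psat1 (-3.20 and -3.76) and Asns (-3.20 and -3.11) and the replication genes Mcm5 (-2.99 and -3.09) and Cdt1 (-2.65 and -2.94).

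Fibroblast markers were lower in CMa than in CMp, with a median log2 change of -3.23 over 19 genes (adjusted p = 0.0552 with an estimated correlation). A smaller cardiomyocyte share in the CMp preparations that raised all other cell types alike was not settled. Endothelial markers changed by a median of -0.92 over 16 genes (permutation p = 0.00015 from permuting genes, not samples). Leukocyte markers changed by -0.91 (-0.77) and smooth muscle markers by -0.25 over 9. Epicardial and erythroid markers changed by -2.52 (-1.50) and -2.35 (-2.05), nearer to the fibroblast markers. Permuting genes treats the markers of a cell type as independent, so that p-value cannot decide the question. More fibroblasts in the CMp preparations, with the same RNA in each, remains open, since 7 matrix genes (median -4.04) and 6 identity genes (median -2.35) did not differ past the threshold (exact permutation p = 0.0967 over 1716 splits). Age of the animals remains open as well, as the change of -3.23 comes with a different heart region and preparation, and age was not tested by itself.

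Splitting the arrays in other ways asked whether any grouping gives counts as large. For each pair of groups 10 splits exist, too few for a share under 0.05, and the real split was the 1 with the largest value. Every other split of a pair mixes arrays of both groups, which puts the real difference into the spread within groups. Low gene counts there follow from that mixing and do not measure chance. Drawn splits of all 9 arrays can mix the real groups in the same way. Changed genes numbered 8012, 8315 and 5651 in the real splits and at most 0, 0 and 57 in the others, those changed at least 2-fold 5709, 6234 and 3143 against at most 0, 0 and 57, and called lists 23, 19 and 12 against at most 22, 18 and 9. Of 100 drawn splits of all 9 arrays 1, the real one, gave as many genes in the F-test (9496, the next 6150), higher in both groups than mES (2927, the next 1550) and lower in both (3478, the next 1997).

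Sex-linked genes differed between the groups, with Xist at 11.02 ± 0.81 in CMp, 4.29 ± 0.02 in mES and 4.37 ± 0.10 in CMa, and the Y-linked Eif2s3y at 10.26 ± 0.28 in mES, 4.47 ± 0.06 in CMp and 4.44 ± 0.07 in CMa. Kdm5d, also Y-linked, was at 4.44 ± 0.25, 5.26 ± 0.28 and 6.57 ± 0.19. Eif2s3y was at background in both heart groups, so it cannot rank CMp against CMa, and its level in mES comes with a different cell type. Between CMp and CMa, all 4 kept Xist probes were lower in CMa (log2 changes of -6.65 to -1.75), and Kdm5d was higher. These values argue against the same mix of sexes in CMp and CMa. The sex of each sample was not settled.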
